A study of Drosophila melanogaster with 40 samples.

How the data were processed

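Whole-fly total RNA of Drosophila melanogaster was measured on 40 Affymetrix expression arrays, 1 array per sample. Per the labels, the flies were the progeny of a cross between a line with a dSTING RNAi hairpin inserted at attP2 and a line with Act5C-GAL4, a driver active throughout the body, over the balancer chromosome CyO. Straight-winged progeny expressed the hairpin (knockdown flies), and curly-winged siblings did not (control flies). Flies aged 4 to 7 days were inoculated in the thorax with a glass needle dipped in PBS (mock), Drosophila C virus (DCV, an RNA virus), insect iridescent virus 6 (IIV6, a DNA virus) or Listeria monocytogenes (an intracellular bacterium), and homogenized 24 or 72 h later. The stocks were 5e7 TCID50/ml for DCV, 5e6 TCID50/ml for IIV6 and 1e7 CFU/ml for Listeria. RNA was extracted with the Qiagen RNeasy kit, checked on an Agilent Bioanalyzer, and labelled with biotin by the Affymetrix 3' IVT Express kit. The sex of the flies and the number per sample are not given in the sources used here.

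The deposited table holds 1 intensity per probe set and array, made by the authors, on a linear scale from 5.848 to 36240. The software, the background correction, the summary of probes and the normalization between arrays are not given in the sources used here. The array medians ran from 83.85 to 127.4 and the upper quartiles from 442.4 to 506.1, so the arrays had been brought to a similar scale, though not to the same distribution. A normalization that compresses dim probe sets would make fold changes of low transcripts too small, and the deposited values do not show how far this was the case. The number of arrays limits the precision: mock groups held 4 arrays and infected groups 2. The labels number the replicates but do not say whether they came from separate batches of flies, so p-values measure the spread between these samples, which may be technical.

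Groups were taken from the titles, with which the descriptions and characteristics coincide. For 4 arrays (control mock 24 h replicates 3 and 4 and knockdown mock 72 h replicates 3 and 4) the source name gives another group than the title. Of 18952 probe sets, 183 control probe sets were left out and 18769 were tested. Gene names came from the platform annotation, and 13544 symbols were updated through their Entrez identifiers with a gene table of Drosophila Release 6, which was used for names and chromosome arms only. There were 13647 probe sets with 1 gene, 402 with several genes, from which no gene was named, and 4720 unnamed ones. Together they covered 11982 genes. Sting had 1 probe set. Where in the transcript that probe set lies relative to the hairpin was not analysed here.

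Log2 values of the deposited intensities were fitted with limma 3.58.1 in R 4.3.3, with lmFit, 1 mean for each of the 16 groups over all 40 arrays and eBayes moderation (24 residual and 2.614 prior degrees of freedom). The 21 contrasts were the knockdown minus control difference averaged over the 8 combinations of inoculum and time, the same difference in mock flies at each time, each inoculum against mock within genotype and time, and the difference of each such response between genotypes (interaction). All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and the threshold was an adjusted p under 0.05. Values are given as log2 change with its standard error (SE). On simulated data with known changes, 86, 90, 100 and 100% of changes of 0.5, 1, 2 and 4 log2 units were recovered for the averaged difference, 44, 70, 98 and 100% for DCV against mock in control flies at 72 h, and 18, 54, 82 and 100% for the DCV interaction at 72 h. The share of false calls there was 5.528, 4.294 and 4.511%. The simulated errors were independent between probe sets and arrays, and no array stood apart. These shares therefore do not show how differences shared by many genes of an array affect the calls.

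The 20 gene lists were Imd antimicrobial peptides, Toll pathway effectors, Imd pathway components and regulators, STING-regulated antiviral genes, JAK-STAT and virus-induced genes, antiviral RNAi and restriction, heat shock proteins, glutathione S-transferases and detoxification, digestive enzymes, lipid metabolism, glycolysis, mitochondrial respiratory chain, autophagy, melanization and clotting, hemocyte markers, ovary and eggshell markers, male reproductive tract markers, muscle markers, eye and neuronal markers, and markers of the cross (genes whose alleles or promoters the parental chromosomes carry or can carry). Of 374 entries, 284 matched a probe set, with 5 of 13 Imd antimicrobial peptides and 6 of 17 heat shock proteins at the low end. A match of Mst57Db to a translation factor, made through an older name, was removed. In the list of 6 STING-regulated genes, the older name chosen for Srg3 turned out to belong to Srg1, and no probe set is annotated to Srg3 itself, so that list was tested with 5 genes. Each gene was represented by the probe set with the highest mean over all arrays. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, adjusted over the 20 lists within a contrast. Of 420 list tests, 126 passed with the preset correlation and 8 with the estimated one.

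Named genes followed a rule: Sting in every comparison, then the probe sets past the threshold with exactly 1 gene, 8 rises and 8 falls of the largest size in the averaged difference and 6 and 6 in every other comparison, and up to 4 members per list with the largest absolute change, those past the threshold first. Groups, contrasts, lists, this rule and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, leaving out the third of probe sets with the lowest mean (under 4.94 on the log2 scale), 1 probe set per gene, trended and robust variances, the replicate number as a block, leaving out or regrouping the 4 arrays with conflicting source names, mock replicates 1 and 2 only, a fit of only the groups compared, and leaving out each array in turn. Where that left 1 array in a group, it was assumed to vary like the other groups. Chosen after seeing the data were leaving out control mock 24 h replicate 3, leaving out replicates 3 and 4, and a covariate for the male reproductive tract list. The chromosome arm of each gene was examined only after the genotype difference had been seen.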

Results

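Gene expression was measured in whole adult flies in which dSTING (Sting, the fly homologue of the innate immune adaptor STING) had been knocked down by RNAi, and in control siblings from the same cross. The stated aim was to find how genotype affects expression after infection. The 40 arrays fell into 16 groups, 1 for each combination of genotype, inoculum (mock, DCV, IIV6 or Listeria) and time (24 or 72 h). Mock groups held 4 arrays and infected groups 2. The median intensity per array lay between 83.85 and 127.4. Each array had a correlation across probe sets of 0.9639 to 0.997 with the array most like it, and of at least 0.9869 once control mock 24 h replicate 3 was set aside. Across arrays, the first principal component held 52.4% of the variance, with eggshell genes such as Cp36, Cp7Fc and yellow-g2 at one end and the maltase Mal-A6, the antimicrobial peptide Mtk and genes of the male germline such as djl, salto and fest at the other.

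The mean Sting level was lower in knockdown than in control flies in all 8 combinations of inoculum and time. The averaged difference was −0.75 (SE 0.076, 20 against 20 arrays, limma adjusted p = 5.564e-08), a 1.68-fold reduction. The depth of the knockdown differed between groups. In DCV flies at 72 h the log2 level was 7.13 ± 0.34 (SD, n = 2) in knockdown and 9.11 ± 0.27 (SD, n = 2) in control flies, so 25.3% of the control level remained (limma adjusted p = 6.371e-06). In mock flies the level was 7.69 ± 0.22 against 8.15 ± 0.36 at 24 h and 8.33 ± 0.20 against 8.75 ± 0.11 at 72 h (SD, n = 4 each), and 72.9% and 74.8% remained. Neither mock difference passed the threshold over all probe sets (limma adjusted p = 0.4167 and 0.6241, unadjusted p = 0.009315 and 0.01576). The values of the genotypes overlapped in mock flies at 24 h, where control replicate 3 stood at 7.63, and in IIV6 flies at 24 h. They overlapped in none of the other 6 combinations. The share that remained was 56.1% in DCV flies at 24 h, 81.7% and 74.7% in IIV6 flies at 24 and 72 h, and 52.5% and 62.5% in Listeria flies. None of these 5 differences passed the threshold (limma adjusted p = 0.2228, 0.4854, 1, 0.1603 and 0.5415).

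**Figure D1:**
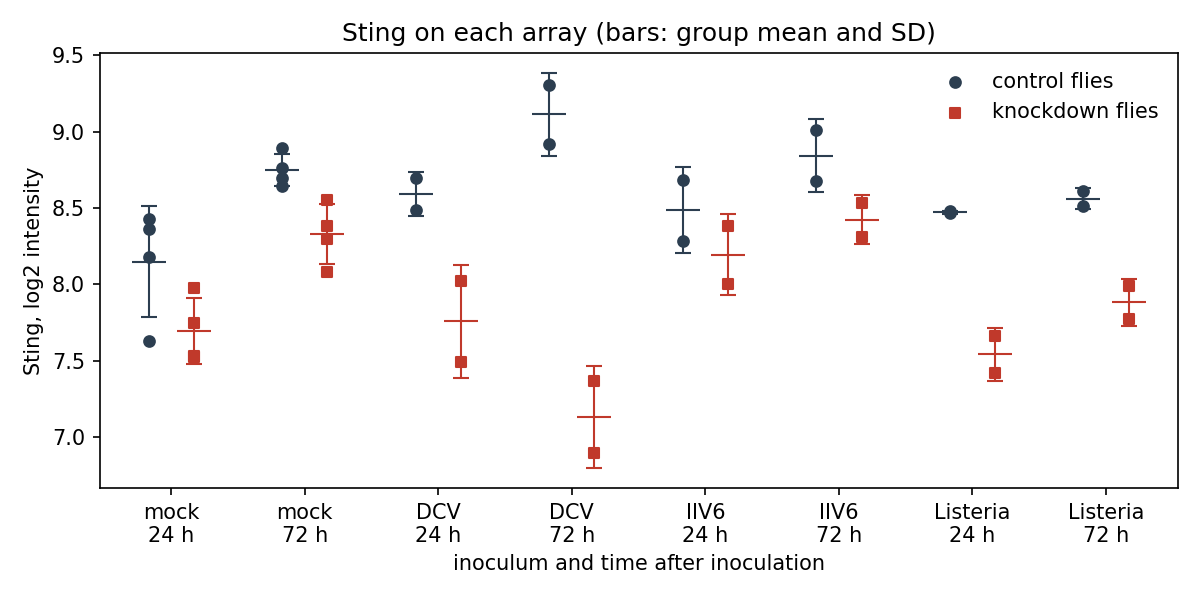
Sting level (log2 intensity, vertical axis) on each of the 40 arrays by inoculum and time (horizontal axis), with circles for control and squares for knockdown flies and bars for the mean and SD of each group. Knockdown lies lowest in DCV flies at 72 h, with a mean of 7.13 against 9.11 in control flies.

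Over all inocula and times, knockdown and control flies differed at 950 probe sets, 621 higher and 329 lower in knockdown flies (limma, 20 against 20 arrays). The pigmentation gene y, of which the labels list the y1 allele and a y+ copy among the parental chromosomes, was higher by 2.64 (SE 0.1147, adjusted p = 1.218e-15). Other higher genes were the peroxiredoxin Prx6c by 1.43 (SE 0.2582), CG30281 by 1.42 (SE 0.0976), CG31809 by 1.36 (SE 0.0669) and the sarcosine dehydrogenase Sardh by 1.21 (SE 0.0971). Lower in knockdown flies were l(3)87Df at −2.83 (SE 0.0497, adjusted p = 4.466e-25) and CG30083 at −2.46 (SE 0.1223). So were the cytochromes P450 Cyp4p2 at −1.56 (SE 0.0578) and Cyp6d2 at −1.43 (SE 0.0631) and the C-type lectin gene lectin-24A at −1.51 (SE 0.169). SCAP, which escorts the lipid regulator SREBP, stood at −1.29 (SE 0.0971), and the odorant-binding protein Obp56a at −1.26 (SE 0.1512). The count was 1145 both without control mock 24 h replicate 3 and without replicates 3 and 4, settings chosen after seeing the data. With a covariate for the male reproductive tract genes, also chosen after seeing the data, it was 1731, 1015 higher and 716 lower.

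Among the lists, 34 of 284 members were higher and 13 lower in knockdown flies. Of 15 genes of the mitochondrial respiratory chain 8 were higher and none lower (11 higher adjusted over the list alone), among them RFeSP by 0.28, ATPsynbeta by 0.24 and ND-42 by 0.21 (camera adjusted p = 1.544e-08, adjusted p = 0.443 with an estimated correlation). Of 20 glutathione S-transferase and detoxification genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone), with GstE7 at 0.87, GstE6 at 0.51, GstE3 at 0.50 and Cyp6a2 at −1.15 (camera adjusted p = 0.001535, adjusted p = 0.9681 with an estimated correlation). Of 5 markers of the cross 2 were higher (3 adjusted over the list alone), y and the eye pigment gene pr at 0.42, and the camera call held with an estimated correlation (adjusted p = 2.823e-07 and 0.004752). Of 5 STING-regulated antiviral genes Srg2 was lower by −0.68 (SE 0.1233, adjusted p = 0.0005898) and cGlr2, a cGAS-like receptor, higher by 0.31 (2 higher and 3 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.4943). Camera also called none of the following lists. Digestive enzymes had 1 higher and 5 lower members of 28 (7 and 7 adjusted over the list alone), with LysX at 1.09 and the maltase Mal-A3 at −1.15, a median of 0.02, a mean of −0.03 and a downward test (adjusted p = 0.5846). Glycolysis had 4 higher and 1 lower of 14, with Gpdh1 at 0.43 and Treh at −0.23. Melanization and clotting had 3 higher of 15, with PPO3 at 0.50. Hemocyte markers had 3 higher and 2 lower of 12 (6 and 3 adjusted over the list alone), with Hml at 0.32 and He at −0.54. Toll effectors had 1 higher, BomS4 at 0.60, and 1 lower of 19, and the Imd pathway had imd at 0.21 and key at −0.12 of 16. Lipid metabolism had 1 higher and 1 lower (SREBP at −0.20) of 18, eye and neuronal markers had 2 higher of 8 (trpl at 0.52) and the JAK-STAT list had et at 0.16 of 13. No member passed in the lists of Imd peptides (median −0.84), antiviral RNAi (median 0.01), heat shock proteins (0.02), autophagy (0.01), ovary (0.18), male reproductive tract (−0.0019, with a mean of 0.02) and muscle (0.15).

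The called genes were not spread evenly over the chromosome arms. Of the tested genes, 259 of 2205 on 2L (11.8%) and 281 of 2427 on 2R (11.6%) were called, against 79 of 2344 on 3L (3.37%), 82 of 2974 on 3R (2.76%), 52 of 1873 on X (2.78%) and 3 of 65 on chromosome 4 (4.62%). Chromosome 2, on which Sting itself lies, held 540 of 756 called genes (71.4%) and 4092 of 11132 other tested genes (36.8%), an odds ratio of 4.301 (95% interval 3.648 to 5.083, Fisher's exact test p = 1.017e-77, across genes, which are not independent replicates). Of the 29 called genes that differed by more than 2-fold, 25 were on chromosome 2. The list members above were not divided by arm. Their counts therefore do not separate a change of a pathway from this concentration on chromosome 2.

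**Figure D2:**
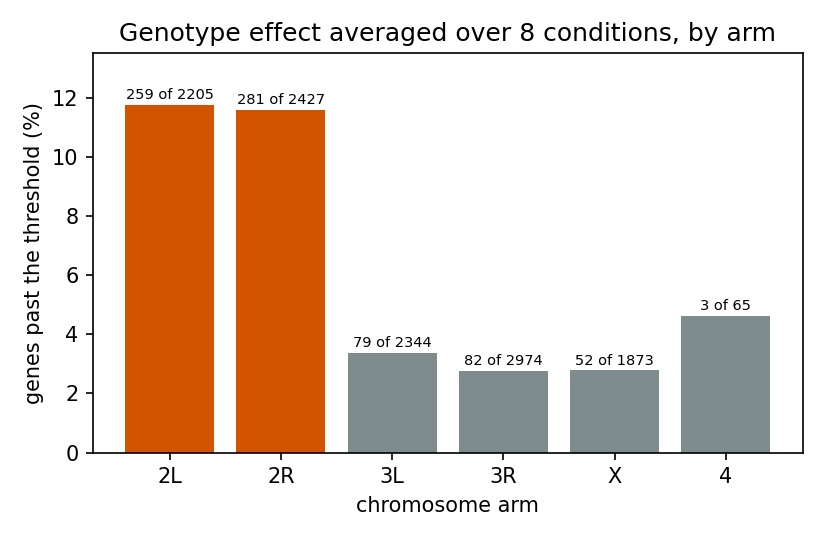
Share of tested genes called between knockdown and control flies (percent, vertical axis) by chromosome arm (horizontal axis), for the difference averaged over inocula and times. Arms 2L and 2R stand at 11.8% and 11.6%, and the other arms between 2.76% and 4.62%.

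In mock flies at 24 h (4 against 4 arrays), Sting was at −0.46 (SE 0.1624), as above, and 116 probe sets passed, 56 higher and 60 lower in knockdown flies. The largest rise was that of the follicle cell gene Fcp3C, which is not on the ovary list, by 3.67 (SE 0.7096, limma adjusted p = 0.006337). Its level was 10.5 ± 1.08 in knockdown and 6.86 ± 1.37 in control flies (SD, n = 4 each). y was higher by 2.29 (SE 0.2453), the lysozyme LysX by 1.78 (SE 0.2826), CG30281 by 1.52 (SE 0.2087), CG2772 by 1.47 (SE 0.1689), the bomanin BomS4 by 0.89 and GstE6 by 0.50. Lower were l(3)87Df at −2.62 (SE 0.1063), CG30083 at −2.51 (SE 0.2616), Cyp4p2 at −1.73 (SE 0.1235), Cyp6a2 at −1.56 (SE 0.2372) and the hemocyte gene He at −0.72. Cross markers had 2 higher of 5 (2 adjusted over the list alone; camera adjusted p = 0.0003258, adjusted p = 0.07183 with an estimated correlation). No member of the ovary list of 20 passed (5 higher adjusted over the list alone), though its median was 2.11 and camera called it (adjusted p = 7.859e-12, adjusted p = 0.519 with an estimated correlation). That list moved with 2 arrays of this group. On control mock 24 h replicate 3 the yolk protein genes averaged 5.44, against 14.3 to 14.6 on the other 3 arrays. The eggshell genes averaged 5.10, and all 25 genes of the male reproductive tract list were higher than the mean of those arrays. On replicate 4 the eggshell genes averaged 8.87 with yolk proteins at 14.3. Without replicate 3, 95 probe sets passed, 80 of them shared with the 116, and without replicates 3 and 4, 76, of which 62 were shared (chosen after seeing the data). Of the 76, 48 were higher and 28 lower in knockdown flies. With the male reproductive tract covariate 123 were higher and 222 lower, so the larger share depended on the setting. In a fit of only these groups 13 passed, 6 higher and 7 lower. With the 4 arrays of conflicting labels grouped by source name, none passed in limma.

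**Figure D3:**
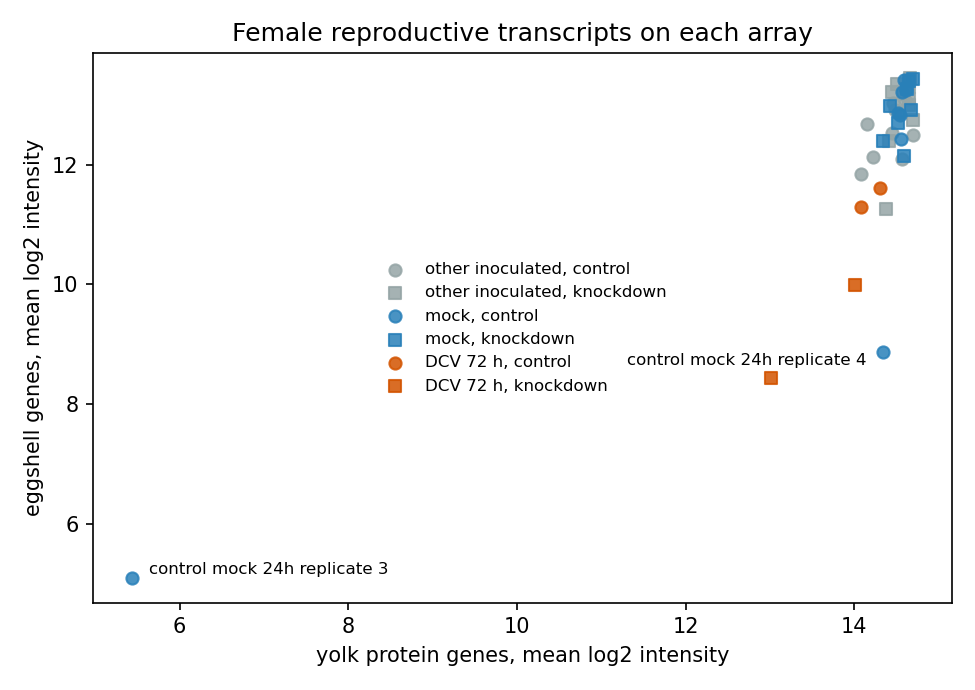
Mean log2 intensity of the yolk protein genes (horizontal axis) against that of the eggshell genes (vertical axis), 1 point per array, with circles for control and squares for knockdown flies and colours for mock, DCV at 72 h and the other inoculated groups. Control mock 24 h replicate 3 lies at 5.44 and 5.10, and the DCV arrays at 72 h have eggshell means of 8.45 and 9.99 in knockdown and 11.3 and 11.6 in control flies.

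In mock flies at 72 h (4 against 4 arrays), Sting was at −0.42 (SE 0.1624), as above, and 44 probe sets were higher and 81 lower in knockdown flies. y was higher by 2.32 (SE 0.2453), CG31955 by 1.47 (SE 0.1926), CG33474 by 1.38 (SE 0.1252), CG2772 by 1.34 (SE 0.1689), CG30281 by 1.26 (SE 0.2087), pr by 0.42 and GstE6 by 0.37. Lower were l(3)87Df at −2.93 (SE 0.1063), CG30083 at −2.17 (SE 0.2616), Cyp4p2 at −1.89 (SE 0.1235), the chitinase Cht9 at −1.74 (SE 0.2748), Cyp6d2 at −1.66 (SE 0.1348) and He at −0.80. Between 24 and 72 h, 35 higher and 39 lower probe sets were shared, where independent lists would share 0.1313 and 0.2589, and none was called in opposite directions. Cross markers had 2 higher of 5 (camera adjusted p = 2.606e-06, 0.0105 with an estimated correlation). The male reproductive tract list had no member past the threshold, also adjusted over the list alone, with a median of 0.53 (camera adjusted p = 4.671e-09, adjusted p = 0.7871 with an estimated correlation). The count was 146 without control mock 24 h replicate 3 and 148 without replicates 3 and 4, and fell to 77, 81 and 83 without knockdown mock 72 h replicate 4 and control mock 72 h replicates 1 and 2. Without the 4 arrays of conflicting labels 40 were higher and 41 lower, and with mock replicates 1 and 2 only 26 and 28. With the male reproductive tract covariate 65 were higher and 126 lower. With the 4 arrays of conflicting labels grouped by source name, 3 passed.

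At 24 h after DCV (2 against 4 arrays), Sting stood at 0.44 (SE 0.1989, adjusted p = 0.4839) in control and 0.06 (SE 0.1989, adjusted p = 0.9798) in knockdown flies, with an interaction of −0.38 (SE 0.2813, adjusted p = 1). No probe set passed in limma in either genotype or in the interaction, and 1922, 503 and 606 had an unadjusted p under 0.05, where chance gives 938. In control flies, 12 of 15 respiratory chain genes fell adjusted over the list alone, with a list median of −0.27 (camera adjusted p = 1.159e-12, adjusted p = 0.3189 with an estimated correlation). The ovary list had a median of 2.26 (camera adjusted p = 2.283e-08, adjusted p = 0.4191 with an estimated correlation) and the muscle list one of −0.61 (6 fell adjusted over the list alone; camera adjusted p = 5.336e-07, adjusted p = 0.4191 with an estimated correlation). All control comparisons at 24 h use control mock replicates 3 and 4 with their low eggshell genes (5.10 and 8.87). In knockdown flies the male reproductive tract list had a median of −0.52 (camera adjusted p = 3.654e-08, adjusted p = 0.8935 with an estimated correlation). In control flies 14, 2 and 7 probe sets passed without control mock 24 h replicate 2, replicate 4 and control DCV 24 h replicate 1. In knockdown flies 2 passed without knockdown mock 24 h replicate 4 and 2 without knockdown DCV 24 h replicate 1, and in the interaction 2 without knockdown DCV 24 h replicate 1 and 1 without control DCV 24 h replicate 1.

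At 72 h after DCV, control flies (2 against 4 arrays) showed 799 higher and 707 lower probe sets, 1506 in all, and Sting at 0.37 (SE 0.1989, adjusted p = 0.2163). The noncoding RNA lncRNA:CR32368 rose by 5.59 (SE 0.4916, adjusted p = 7.003e-09), CG42807 by 4.78 (SE 0.5715), CG7763 by 4.68 (SE 0.5243), CG32302 by 4.63 (SE 0.3922), the STING-regulated gene Srg2 by 4.58 (SE 0.3228, adjusted p = 2.94e-10) and CG14957 by 4.54 (SE 0.6492). The fatty acid elongase eloF changed by −7.18 (SE 0.9044, adjusted p = 2.688e-06) and the eggshell gene yellow-g2 by −6.36 (SE 1.2272, adjusted p = 0.0008269). The count was 3650 without control mock 24 h replicate 3 and 3505 without replicates 3 and 4, both including all 1506. In a fit of only these groups it was 5776, 2785 higher and 2991 lower, and with quantile normalization 744 were higher and 921 lower, so that the larger share changed sides. It was 632 without control DCV 72 h replicate 1 and 967 without replicate 2.

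Of 5 STING-regulated antiviral genes, 4 rose in control flies 72 h after DCV (4 adjusted over the list alone), Srg2, Srg1 by 2.67, Nazo by 1.56 and cGlr2 by 0.61, the last pair not passing at 1.31 and 0.41 without control DCV 72 h replicate 1. Camera called the list with the preset and with an estimated correlation (adjusted p = 7.49e-07 and 0.002502). The JAK-STAT and virus-induced list had 3 risers of 13 (4 and 1 faller adjusted over the list alone), among them vir-1, a marker of virus infection, by 3.64 (camera adjusted p = 0.02026, adjusted p = 0.2673 with an estimated correlation). Heat shock proteins had 2 risers of 6 (2 adjusted over the list alone), Hsp68 by 3.30 and the co-chaperone stv by 1.93 (camera adjusted p = 0.02026, adjusted p = 0.3072 with an estimated correlation), with a list median of 0.12 that was −0.0063 without control DCV 72 h replicate 1. Toll effectors had 4 risers of 19 (8 and 1 faller adjusted over the list alone), among them Drsl3 by 2.10 (camera adjusted p = 0.0005642, adjusted p = 0.4364 with an estimated correlation). Hemocyte markers had 3 risers of 12, with He by 1.14 (adjusted p = 0.01501, adjusted p = 0.4364 with an estimated correlation). Melanization and clotting had 2 of 15, with the protease Sp7 by 0.86 (adjusted p = 0.03872, adjusted p = 0.5385 with an estimated correlation). Detoxification had 2 risers and 1 faller of 20, with Cyp6a8 by 1.93 (adjusted p = 0.03831, adjusted p = 0.6412 with an estimated correlation), and with the male reproductive tract covariate the median of that list turned from 0.22 to −0.11. Of 28 digestive enzymes 6 rose and 11 fell (6 and 13 adjusted over the list alone), with the serine protease Jon25Bii at −3.04 (camera adjusted p = 0.01544, adjusted p = 0.5385 with an estimated correlation). Male reproductive tract genes had a median of 1.06 and 10 of 25 risers adjusted over the list alone but none over all probe sets (camera adjusted p = 1.211e-06, adjusted p = 0.5385 with an estimated correlation). Camera did not call the ovary list (1 of 20 fell, median −0.80), the Imd pathway (2 rose, key by 0.59) or autophagy (2 rose, Atg8a by 0.42). Nor did it call antiviral RNAi (pst rose by 0.89; median −0.16 and an upward test), glycolysis (1 rose, 2 fell) or lipid metabolism (2 rose, the lipase Lip4 by 1.55 and the carnitine palmitoyltransferase whd by 0.78, and 4 fell; median −0.13 and an upward test).

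In knockdown flies at 72 h after DCV (2 against 4 arrays) Sting fell by 1.20 (SE 0.1989, adjusted p = 5.586e-05), and 4529 probe sets passed, 2224 higher and 2305 lower. CG14957 rose by 5.47 (SE 0.6492), CG7763 by 4.78 (SE 0.5243), the cold- and stress-induced gene Fst by 4.67 (SE 0.4833, adjusted p = 4.378e-08), mat by 4.52 (SE 0.4132), CG14219 by 4.45 (SE 0.3495) and the stress peptide TotC by 4.31 (SE 0.8978). eloF changed by −6.90 (SE 0.9044), the eggshell genes Cp7Fc by −6.32 (SE 1.3829), dec by −6.28 (SE 1.0308), Vm32E by −6.27 (SE 0.9494) and yellow-g2 by −6.24 (SE 1.2272), and the odorant-binding protein Obp19c by −5.70 (SE 0.9883). Of the 799 and 707 probe sets called in control flies, 716 and 387 were also called in knockdown flies in the same direction, where independent lists would share 94.7 and 86.8, and 6 and 6 in the opposite one. In a fit of only the groups compared, 5286 passed in knockdown flies, 3783 of them shared with the 4529, against 5776 in control flies. Which genotype had the larger count thus depended on the setting. The count in knockdown flies was 5848 without control mock 24 h replicate 3 and 5813 without replicates 3 and 4. It was 2043 without knockdown DCV 72 h replicate 1, and 1724 with the 4 arrays of conflicting labels grouped by source name, where Cp7Fc, yellow-g2 and Obp19c did not pass.

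In these knockdown flies, most members of several immune and blood cell lists rose. Of 19 Toll effectors 13 rose and 1 fell (15 and 1 adjusted over the list alone), with the bomanin BomBc3 by 2.30 and Drsl3 by 1.57 (camera adjusted p = 2.574e-05, adjusted p = 0.1974 with an estimated correlation). Of 15 melanization and clotting genes 10 rose (10 adjusted over the list alone), with the serpin Spn28Dc by 2.82, yellow-f by 1.63 and Sp7 by 1.52 (adjusted p = 7.57e-06, adjusted p = 0.08354 with an estimated correlation). Of 12 hemocyte markers 9 rose (9, and 1 fell, adjusted over the list alone), with the phagocytosis receptor NimC1 by 1.49, He by 1.10 and Ppn by 0.99 (adjusted p = 0.0001359, adjusted p = 0.1254 with an estimated correlation). Of the STING-regulated genes 4 of 5 rose (5 adjusted over the list alone), with Srg2 by 2.08, Srg1 by 1.81 and cGlr2 by 1.27 (adjusted p = 0.0002669, adjusted p = 0.05899 with an estimated correlation). JAK-STAT and virus-induced genes had 7 risers of 13, with vir-1 by 3.45 and Tep4 by 1.22 (adjusted p = 0.01083, adjusted p = 0.1206 with an estimated correlation). Detoxification had 9 of 20 (11, and 1 faller, adjusted over the list alone), with Cyp6a8 by 2.10 and GstD2 by 1.69 (adjusted p = 0.000205, adjusted p = 0.4292 with an estimated correlation). Of 28 digestive enzymes 6 rose and 14 fell (8 and 14 adjusted over the list alone), with the maltases Mal-A7 by 3.69 and Mal-A1 by 3.39 and the protease Jon66Ci at −5.13 (adjusted p = 0.01083, adjusted p = 0.5093 with an estimated correlation). Of 20 ovary genes 8 fell and 1 rose, with a median of −1.92 (adjusted p = 0.000399, adjusted p = 0.6429 with an estimated correlation). All 8 fallers were among the 12 eggshell genes, whose median was −4.47, against −1.02 for the other 8 genes, which include the yolk proteins. In control flies these medians were −1.21 and −0.46. Eye and neuronal markers had 2 risers of 8 (4 adjusted over the list alone), with Arr2 by 0.53 (adjusted p = 0.01706, adjusted p = 0.6092 with an estimated correlation).

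Camera did not call the remaining lists in knockdown flies at 72 h after DCV. The Imd pathway had 5 risers and 1 faller of 16 (7 and 1 adjusted over the list alone), with the NF-kappaB factor Rel by 1.68 and the caspase Dredd by 0.54. Imd peptides had 2 risers of 5, of which CecB, at 2.81, was at 1.44 and did not pass without knockdown DCV 72 h replicate 1. Heat shock proteins had 2 risers and 2 fallers of 6, with Hsp68 by 3.29, stv by 2.39 and Hsp27 at −1.64 (median −0.05, mean 0.53, upward test). Lipid metabolism had 4 risers and 3 fallers of 18, with Lip4 by 1.64 and Lpin by 0.84. Antiviral RNAi had pst at 0.98 and 2 fallers of 8, r2d2 at −0.97 among them. Autophagy had 3 risers of 17, with Atg8a by 0.42. Glycolysis had 1 riser, Pepck1 by 1.34, and 1 faller of 14 (median −0.04, mean 0.08, downward test). Of the respiratory chain 1 of 15 fell, and of the cross markers 1 rose and 2 fell (median 0.11, mean −0.08). Of the muscle list 1 of 15 rose and 0 adjusted over the list alone (median −0.01, mean 0.07), and of the male reproductive tract list none passed (median 0.32).

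**Figure D4:**
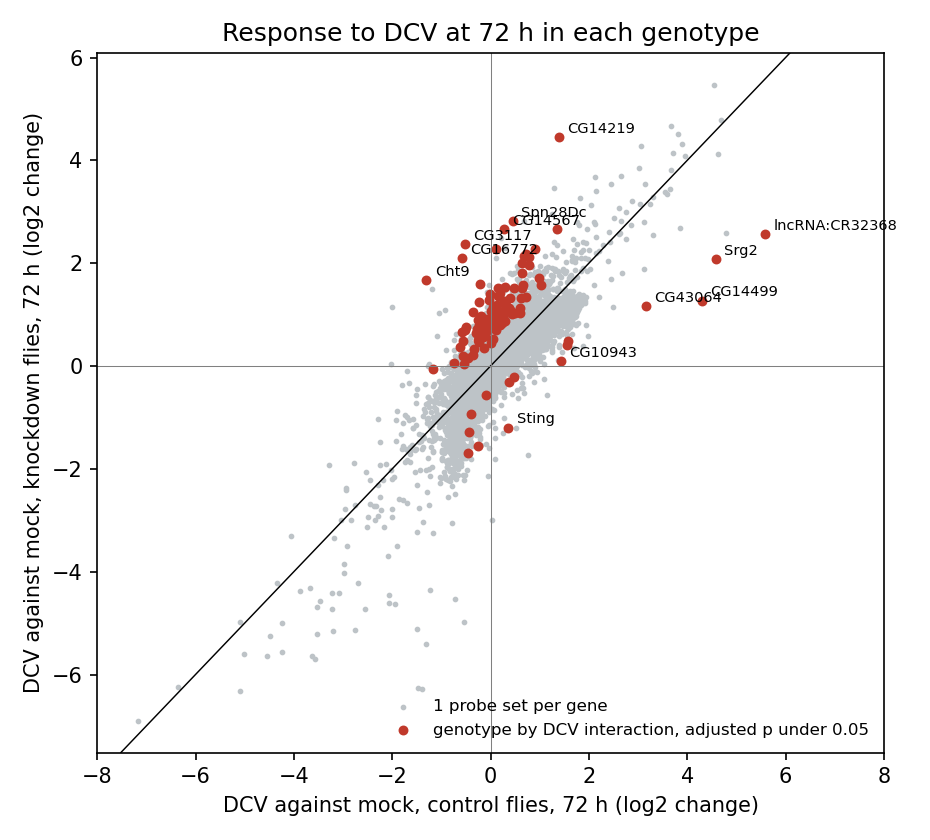
Log2 change after DCV at 72 h in control flies (horizontal axis) against that in knockdown flies (vertical axis), 1 probe set per gene, with the genes of the interaction past the threshold in red, named examples marked and a line where both changes are equal. Srg2 lies at 4.58 and 2.08 and CG14219 at 1.38 and 4.45.

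The response to DCV at 72 h differed between the genotypes at 126 probe sets, 111 higher and 15 lower in knockdown flies (limma interaction, 2 and 2 DCV against 4 and 4 mock arrays). Sting had an interaction of −1.56 (SE 0.2813, adjusted p = 0.006091), which at −1.33 no longer passed without knockdown DCV 72 h replicate 1 (adjusted p = 0.06682). Srg2 rose by 4.58 in control and 2.08 in knockdown flies, a difference of −2.50 (SE 0.4565, adjusted p = 0.007084). CG14499 rose by 4.30 and 1.27 (difference −3.02, SE 0.5471) and CG43064 by 3.17 and 1.17 (difference −1.99, SE 0.2951, adjusted p = 0.001504). The opposite held for CG14219, with 1.38 in control and 4.45 in knockdown flies (difference 3.06, SE 0.4943, adjusted p = 0.002282), CG3117, with −0.52 and 2.37 (difference 2.88, SE 0.5175), and the chitinase Cht9, with −1.30 and 1.68 (difference 2.98, SE 0.4759). Of the 111 higher probe sets, 106 rose in knockdown flies, 22 rose in both genotypes and 10 fell in control flies. Of the 15 lower ones, 9 rose in control flies and 7 fell in knockdown flies. Melanization and clotting had 2 higher members of 15 (7 adjusted over the list alone), among them Spn27A, a serpin that restrains melanization, by 1.06 (camera adjusted p = 2.21e-06, adjusted p = 0.123 with an estimated correlation). Of the STING-regulated genes Srg2 alone passed among 5 (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.2557). Hemocyte markers had 1 higher member of 12 (adjusted p = 0.01384, adjusted p = 0.6409 with an estimated correlation) and detoxification none of 20 (2 adjusted over the list alone; adjusted p = 0.004896, adjusted p = 0.6409 with an estimated correlation). The ovary list had a median of −1.11 (3 lower adjusted over the list alone; camera adjusted p = 5.489e-05, adjusted p = 0.6409 with an estimated correlation) and the male reproductive tract list one of −0.72 (adjusted p = 5.406e-05, adjusted p = 0.7125 with an estimated correlation). The count was 238 without control mock 24 h replicate 3 and 237 without replicates 3 and 4. It was 253 and 31 without control DCV 72 h replicates 1 and 2, 54 without knockdown DCV 72 h replicate 1 and 68 without knockdown mock 72 h replicate 4. With mock replicates 1 and 2 only it was 48 (33 higher and 15 lower), in a fit of only these groups 52 (28 and 24), and by source name 58 (48 and 10). CG14219, CG3117, CG14499 and Srg2 did not pass under the first of these settings, CG14219, CG14499 and Spn27A under the second, and Cht9 under the third. CG43064 passed under all of them. With the male reproductive tract covariate the count was 860, 493 higher and 367 lower.

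After IIV6 (2 against 4 arrays), Sting stood at 0.34 and 0.09 in control and 0.50 and 0.09 in knockdown flies at 24 and 72 h (SE 0.1989), with interactions of 0.16 and −0.0027 (SE 0.2813), none past the threshold. At 24 h limma called 0 probe sets in control and 0 in knockdown flies, with 1123 and 2004 at an unadjusted p under 0.05. With mock replicates 1 and 2 only, 3791 passed in knockdown flies and 1 in control flies at 24 h. At 72 h it called 3 in control flies, CG17751 at −1.88 (SE 0.2949, adjusted p = 0.01628), CG2680 at −0.61 and CG31373 at −0.58, and 1 in knockdown flies, CG15263 at 1.68 (SE 0.2642, adjusted p = 0.01664), with 756 and 357 at an unadjusted p under 0.05. Neither interaction had a call in limma (679 and 238 at an unadjusted p under 0.05). In control flies at 72 h the muscle list had a median of −0.46 (camera adjusted p = 1.287e-08, adjusted p = 0.2838 with an estimated correlation), and the respiratory chain one of −0.13 (adjusted p = 2.33e-07, adjusted p = 0.2838 with an estimated correlation). Hemocyte markers had a median of −0.24 (2 fell adjusted over the list alone; adjusted p = 5.378e-06, adjusted p = 0.2142 with an estimated correlation). In knockdown flies at 72 h muscle had −0.38 (adjusted p = 1.105e-09, adjusted p = 0.4235 with an estimated correlation) and the respiratory chain −0.15 (adjusted p = 4.575e-09, adjusted p = 0.4235 with an estimated correlation). In control flies at 24 h muscle had −0.68 (9 of 15 fell adjusted over the list alone; adjusted p = 2.15e-11, adjusted p = 0.2149 with an estimated correlation). The ovary list had a median of 2.27 there, against mock arrays 3 and 4 with eggshell means of 5.10 and 8.87 (adjusted p = 1.226e-11, adjusted p = 0.2149 with an estimated correlation). In knockdown flies at 24 h the male reproductive tract list had −1.05 (adjusted p = 1.553e-14, adjusted p = 0.3522 with an estimated correlation).

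Single arrays decided the calls after IIV6. In control flies at 72 h, 0 probe sets passed without control mock 72 h replicate 1, without replicate 2 and without control IIV6 72 h replicate 2, 1 without mock replicate 3 and 1 without replicate 4, and 17 without control IIV6 72 h replicate 1. CG17751 was then at −1.73, −1.81 and −1.63 in the first 3 of these. CG2680 and CG31373 did not pass when any of the 6 arrays was left out (−0.72 to −0.51 and −0.61 to −0.54). In knockdown flies at 72 h CG15263 did not pass without knockdown mock 72 h replicate 2 (1.56) or knockdown IIV6 72 h replicate 1 (1.31), with 0 calls each, and 2 probe sets passed without knockdown mock 72 h replicate 1. At 24 h, 16 passed without control mock 24 h replicate 2, 1 without replicate 4 and, in knockdown flies, 2 without knockdown mock 24 h replicate 3. The interactions had 1 call without knockdown mock 24 h replicate 3 and 5 without control IIV6 72 h replicate 1.

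At 72 h after Listeria, control flies (2 against 4 arrays) had 24 higher and 2 lower probe sets, and Sting stood at −0.19 (SE 0.1989, adjusted p = 0.6678). lncRNA:CR32368 rose by 4.65 (SE 0.4916, adjusted p = 5.064e-06), the antibacterial peptide CecB by 4.59 (SE 0.7031, adjusted p = 0.00265), the serine protease spirit, of the Toll cascade, by 3.09 (SE 0.2924, adjusted p = 9.434e-07) and Srg1 by 1.98. Of 5 Imd antimicrobial peptides 3 rose, CecB, AttD by 7.37 (SE 1.4782, adjusted p = 0.03257) and edin by 7.16 (SE 1.3879, adjusted p = 0.02775), and all 5 adjusted over the list alone, with a list median of 5.40. Of 19 Toll effectors none passed and 15 rose adjusted over the list alone, with a median of 0.81. Both calls held with an estimated correlation (camera adjusted p = 1.26e-13 and 2.575e-14, 0.01087 and 0.01743 with an estimated correlation). The Imd pathway had 1 riser of 16 (6 and 1 faller adjusted over the list alone; adjusted p = 0.0007439, adjusted p = 0.2531 with an estimated correlation). The STING-regulated list had 1 of 5, Srg1 (2 adjusted over the list alone; adjusted p = 0.002449, adjusted p = 0.07697 with an estimated correlation), and melanization and clotting had 1 of 15 (3 adjusted over the list alone; adjusted p = 0.0004339, adjusted p = 0.1624 with an estimated correlation). Hemocyte markers had a median of −0.29 (3 fell adjusted over the list alone; adjusted p = 0.0003541, adjusted p = 0.1624 with an estimated correlation). The male reproductive tract list had one of 0.81 (adjusted p = 1.724e-08, adjusted p = 0.4124 with an estimated correlation) and muscle one of 0.36 (adjusted p = 0.0001603, adjusted p = 0.4147 with an estimated correlation). The count was 39 without control mock 24 h replicate 3 and 43 without replicates 3 and 4. With mock replicates 1 and 2 only it was also 39, but only 8 of these were among the 26. In a fit of only these groups it was 31, with 15 among the 26. With the replicate number as a block it was 626, 184 higher and 442 lower. It was 9, 10, 9 and 17 without control mock 72 h replicates 1 to 4, 86 without control Listeria 72 h replicate 1 and 2 without replicate 2. CecB (4.35) and Srg1 (1.92) did not pass without the last of these, and AttD (7.02 to 7.70) and edin (6.62 to 7.69) not without any of the 6 arrays.

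**Figure D5:**
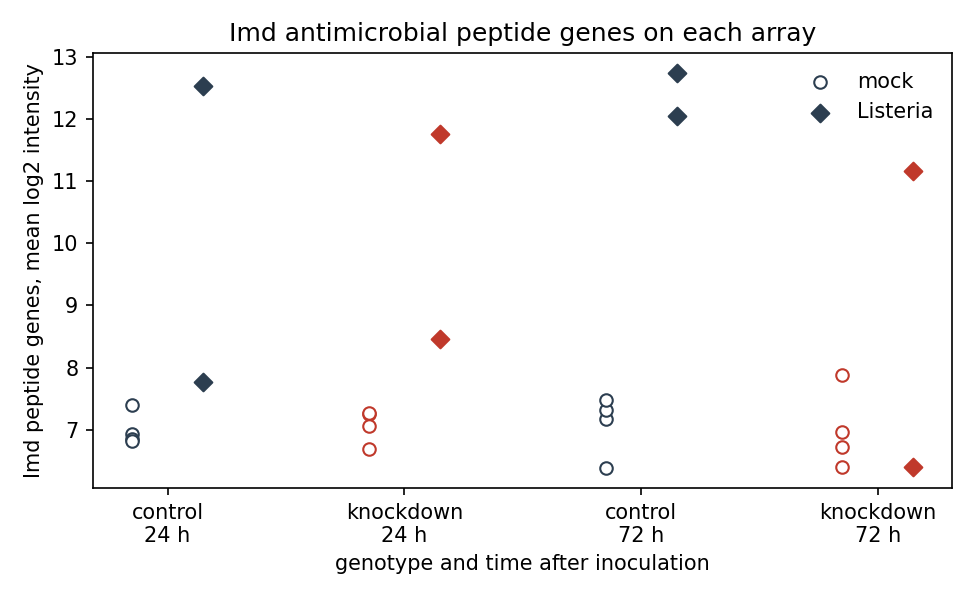
Mean log2 intensity of the 5 measured Imd antimicrobial peptides (vertical axis) by genotype and time (horizontal axis), 1 point per array, with open circles for mock and filled diamonds for Listeria, dark for control and red for knockdown flies. The Listeria arrays lie 4.97 and 5.66 above the mock mean in control flies at 72 h and −0.60 and 4.18 from it in knockdown flies.

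In the other comparisons of Listeria with mock no probe set passed, but calls depended on the model. With the replicate number as a block, 210 passed in control flies at 24 h and 36 and 104 in knockdown flies at 24 and 72 h. With mock replicates 1 and 2 only, 16, 131 and 33 passed. Sting stood at 0.32 in control flies at 24 h and at −0.15 and −0.45 in knockdown flies at 24 and 72 h (SE 0.1989), with interactions of −0.47 and −0.26 (SE 0.2813), none past the threshold. Limma called 0 probe sets in control flies at 24 h (1926 at an unadjusted p under 0.05; 5 called without control Listeria 24 h replicate 1), 0 in knockdown flies at 24 h (597) and 0 at 72 h (781). The 5 Imd peptides had a median of 2.78 in control flies at 24 h (5 rose adjusted over the list alone; camera adjusted p = 1.543e-05, adjusted p = 0.239 with an estimated correlation). The median was 3.25 in knockdown flies at 24 h (4 adjusted over the list alone; adjusted p = 1.508e-09, adjusted p = 0.05123 with an estimated correlation) and 2.14 in knockdown flies at 72 h (0 adjusted over the list alone; adjusted p = 0.00478, adjusted p = 0.7153 with an estimated correlation). The medians rested on single arrays: 0.86 without control Listeria 24 h replicate 2, 1.66 without knockdown Listeria 24 h replicate 1, and 5.01 and −0.61 without knockdown Listeria 72 h replicates 1 and 2. The mean of these peptides minus the mock mean was 0.76 and 5.53 on the 2 control arrays at 24 h, 4.68 and 1.39 on the knockdown arrays at 24 h, and −0.60 and 4.18 on those at 72 h. The ovary list had a median of 2.02 in control flies at 24 h, against the mock arrays with eggshell means of 5.10 and 8.87 (camera adjusted p = 3.93e-06, adjusted p = 0.5539 with an estimated correlation).

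The response to Listeria at 72 h differed between genotypes at 1 probe set, that of spirit, lower in knockdown flies by −2.85 (SE 0.4135, limma adjusted p = 0.004317), with 276 at an unadjusted p under 0.05. It did not pass without knockdown Listeria 72 h replicate 1 (−2.36) or control Listeria 72 h replicate 2 (−2.37), with 0 calls each, and 2 and 24 probe sets passed without knockdown Listeria 72 h replicate 2 and control Listeria 72 h replicate 1. Camera called the Imd peptides (median −3.71, 2 of 5 lower adjusted over the list alone), the Toll effectors (−0.51, 0 of 19) and the Imd pathway (−0.13, 2 of 16) lower in knockdown flies. These calls held with an estimated correlation (adjusted p = 0.02096, 0.02096 and 0.04302). On the knockdown Listeria arrays at 72 h the peptide mean minus the mock mean was −0.60 on replicate 1 and 4.18 on replicate 2. Without replicate 1 the median change of the peptides in knockdown flies was 5.01, near the 5.40 of control flies. Fry did not call the Imd peptides or the Imd pathway (adjusted p = 0.3869 for both), and no member passed over all probe sets. At 24 h limma called 0 probe sets in the interaction, with 384 at an unadjusted p under 0.05.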

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

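The tests on the ovary transcripts, on chromosome 2, on the sexes, on eggshell genes and on the Sting loss with probe sets called from other combinations were chosen only after the results were seen, while the first test on the depth of the Sting loss and the comparisons with other splits of the samples were planned, except that the split without control mock 24 h replicate 3 was prompted by the split with it.

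Control mock 24 h replicate 3 lacked ovary transcripts. The ovary genes outside the eggshell, yolk proteins among them, had a median difference of −6.98 from the other 3 arrays of the group, and the male reproductive tract genes were higher in 25 of 25, so a pool with almost no females is a candidate explanation that has the values it needs. The source names of the 4 arrays with conflicting labels were tested as the true genotype on 741 genes that separate the genotypes. The disputed array nearest to the middle of that scale stood 0.5067 on the side of its title, and the disputed arrays had scores of −0.583, −0.5067, 0.8686 and 0.8293, so the tables argue against the source names. No biological explanation was tested, since all arrays of this group share their genotype, inoculum and time.

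Genotype calls were concentrated on chromosome 2, which held 71.4% of called genes. The tables argue against unequal shares of males and females as the whole cause, since the mean of the male reproductive tract genes differed by 0.02 between the genotypes. With this mean as a covariate 100% of the 950 calls passed. A covariate so evenly balanced between the genotypes could hardly remove calls, so this result adds no evidence. The covariate moved the interaction with DCV at 72 h from 126 to 860 probe sets. The tables also argue against a loss of Sting that acts in proportion to its depth. In DCV flies at 72 h, where Sting was lowest against control flies, the called differences had a slope of 0.9163 on those in mock flies at 72 h (0.8205 to 1.0018 over 1000 bootstraps of 950 probe sets, not of arrays). These probe sets were chosen by an average that includes both groups, but for 601 called from the other 6 combinations of inoculum and time the summed differences in DCV flies were 1.0988 times those in mock flies (1.0544 to 1.1432 without each of the 12 arrays in turn). Both values are taken over many probe sets, so a part of the calls that scales with the depth of the loss stays open. Probe sets that differ only in DCV flies at 72 h would not be among the 601. Sequence differences between the second chromosomes of the siblings, which carried either the driver or the balancer, are a candidate explanation. The 71.4% is the pattern to be explained and not a separate test of these differences. A part from the sexes (the mean of the ovary list differed by 0.20), an effect of Sting that needs only a small loss, and the driver and the hairpin, untested apart from Sting, also stay open.

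After DCV at 72 h, 8 of 12 eggshell genes fell in knockdown and 1 of 12 in control flies, and no ovary gene passed in the interaction, whose camera call ended with an estimated correlation (adjusted p = 0.6409). Fewer females in the DCV pools would lower the other ovary genes as much, and in knockdown flies the eggshell median was lower than theirs by −3.45, which argues against this. In control flies the mean of the eggshell genes minus that of the others was −1.02 to −0.75 on the DCV and 0.28 to 0.84 on the mock arrays at 72 h, which goes against fewer females. The difference of the medians was −0.76, short of the bound set for excluding them, so they stay open there (the test was first run over both genotypes together and then split). Differences in egg stage that are unrelated to DCV remain a candidate explanation, since control mock 24 h replicate 4 had an eggshell mean lower by −2.75 than the highest DCV array (8.87 against 11.6). This rests on that array, and the next-lowest mock array stood at 12.1. Both are 24 h arrays, while the DCV arrays are from 72 h. At 72 h the mock arrays stood between 12.8 and 13.4, all above the highest DCV array.

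Other splits of the samples tested whether chance can be excluded for the genotype calls. For mock flies at 24 h the splits alone did not exclude it, since 3 of 35 gave as many calls as the real 116, and 1 of them gave 3678, which points to a structure of the arrays. Without control mock 24 h replicate 3, 3 of 35 splits gave as many as the real 95, with 333 at the highest. The separate mock arrays at 72 h argue against chance for these calls as a set: 35 of the higher and 39 of the lower calls of the 116 were called there too, where independent lists would share 0.1313 and 0.2589, none was opposite, and 116 of 116 had the same sign. This holds for the called probe sets only, as over all probe sets the differences at 24 and 72 h had a Pearson correlation of −0.0144. Of the 95 calls, 80 were among the 116, but these fits share every array except the one left out, so this overlap does not bear on chance. For mock flies at 72 h, 1 of 35 splits, the real one, reached the real count, with 14 at the highest of the others. For the averaged difference 1 of 100 reached 950, with 19 at the highest of the others. Both results argue against chance. For mock flies at 72 h, 1 of 35 is the smallest share that the splits can give. The splits also treat the samples as independent, which the labels do not state.

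Of 84 tests for an array far from the other 3 of its group on the mean of a gene list or on Sting, 3 found one. As chance gives about 1 in 20, this is no excess. Control mock 24 h replicate 3 stood apart in the antiviral RNAi list by −0.6915 and in the eye and neuronal list by 0.4927. Control mock 72 h replicate 3 stood apart in the Imd pathway list by −0.2128. The ovary list did not flag control mock 24 h replicate 3, as replicate 4 was low too (−7.07 and −2.09 from the mean over all arrays).

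The interaction with DCV at 72 h, with 126 probe sets, picked out differences between the genotypes' responses. They were higher in knockdown flies for CG14219 (3.06), Cht9 (2.98), CG3117 (2.88), CG16772 (2.68), CG14567 (2.40) and Spn28Dc (2.36). They were lower for CG14499 (−3.02), lncRNA:CR32368 (−3.02), Srg2 (−2.50), CG43064 (−1.99), Sting (−1.56) and CG10943 (−1.33). The interaction with Listeria at 72 h picked out 1 probe set, spirit at −2.85.

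Between 24 and 72 h the response to DCV differed at 1120 probe sets in control and 2884 in knockdown flies, and the response to Listeria at 1 probe set in control flies. Without control mock 24 h replicate 3 these DCV counts were 740 in control and 4697 in knockdown flies, and without replicates 3 and 4 they were 511 and 4708.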

How the results depend on the processing

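The settings without control mock 24 h replicate 3, without replicates 3 and 4, and with the male reproductive tract covariate were chosen only after results were seen. Of 236 named gene calls none reversed, and 130 held in every setting, where the fits with 1 array left out are not counted. In those fits a part of the calls no longer passed. Of 200 counts with 1 array left out, 158 were within 1.5 times the reported count. The 158 include counts of 0 that stayed at 0, so they overstate how many sets of calls held. The 51 list medians had 1326 alternatives, of which 1298 moved by less than the spread between arrays, 24 moved by more and 4 reversed. Sting in the averaged difference passed in 51 of 51 settings, here with the fits with 1 array left out counted, between −0.79 and −0.72.

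The replicate number as a block gave 2287 probe sets for DCV in control flies at 72 h, 210 and 626 for Listeria in control flies at 24 and 72 h, 36 and 104 in knockdown flies, and 1 for IIV6 in knockdown flies at 24 h. In deviations from the group means, the median correlation across probe sets was 0.0658 over 252 pairs of arrays with the same number, of which 107 were above 0.1, and −0.0175 over 492 other pairs. For 13 of 40 arrays the closest array of another group had the same number, so the numbers were not taken as pairing. This check does not address a division of the mock arrays into sets. In every mock group the upper quartile was higher on replicates 1 and 2 than on 3 and 4, in knockdown flies at 72 h 499.8 and 498 against 452 and 471.4. The Listeria arrays ran from 442.4 to 460.8. The cause of these differences and of the changed counts was not tested.

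Leaving out the 4 arrays with conflicting labels gave 74 and 81 for the genotypes in mock flies at 24 and 72 h, 3406 for DCV in control flies at 72 h, 0 for IIV6 in knockdown flies at 72 h and 0 for the Listeria interaction at 72 h. Grouping them by source name gave 0 and 3 for mock flies, 1 for IIV6 in control flies at 72 h, 1724 for DCV in knockdown flies at 72 h and 58 for its interaction, and the ovary median in knockdown DCV flies at 72 h was then 0.33. On the genotype scale above, these 4 arrays lay on the side of their titles (−0.583, −0.5067, 0.8686 and 0.8293). By these scores, grouping by source name mixes the genotypes. The comparison of DCV with mock in control flies at 72 h holds none of these 4 arrays, so they enter it only through the pooled variance. The cause of the other changes without the 4 arrays was not tested.

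Using mock replicates 1 and 2 only leaves fewer arrays. Some counts fell and others rose, and the cause was not tested. This setting gave 72 and 54 for mock flies, 2299 for DCV in control flies at 72 h, 1 for IIV6 and 16 for Listeria in control flies at 24 h, and 3791 and 0 for IIV6 in knockdown flies at 24 and 72 h. It gave 131 and 33 for Listeria in knockdown flies, 48 for the DCV interaction at 72 h, 1 for the IIV6 interaction at 24 h and 0 for that with Listeria at 72 h. A fit of only the groups compared gave 13 for mock flies at 24 h, 5776 for DCV in control flies at 72 h, 52 for its interaction, 0 for IIV6 at 72 h in control and 0 in knockdown flies, and 0 for the Listeria interaction at 72 h.

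Without control mock 24 h replicate 3 the counts were 3650 for DCV in control flies at 72 h and 238 for its interaction. Without replicates 3 and 4 they were 76 for mock flies at 24 h, 3505 for DCV and 43 for Listeria in control flies at 72 h, and 237 for the DCV interaction. These 24 h arrays enter the comparisons at 72 h only through the pooled variance. The covariate gave 1731 for the averaged difference, 345 and 191 for mock flies, 1 for DCV and 1 for Listeria in control flies at 24 h, 6 for IIV6 and 11 for Listeria in control flies at 72 h, and 860 for the DCV interaction at 72 h. With it the detoxification median in control DCV flies at 72 h was −0.11. The cause of the changes with the covariate was not tested.

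Leaving out dim probe sets, 1 probe set per gene, and trended and robust variances each gave 1 for DCV in control flies at 24 h. Leaving out dim probe sets gave 0 for IIV6 in knockdown flies at 72 h, and quantile normalization gave 5 for IIV6 in control flies at 72 h. Signal over background limits what the dimmest probe sets can show.

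With each array left out in turn, the counts ran from 785 to 1145 for the averaged difference, 81 to 117 and 77 to 97 for mock flies, 0 to 14 and 632 to 1310 for DCV in control flies at 24 and 72 h, and 0 to 2 and 2043 to 4834 in knockdown flies. For IIV6 they ran from 0 to 16 and 0 to 17 in control and 0 to 2 and 0 to 2 in knockdown flies. For Listeria they ran from 0 to 5 and 2 to 86 in control flies and stayed at 0 in knockdown flies. The interactions ran from 0 to 2 and 31 to 253 for DCV, 0 to 1 and 0 to 5 for IIV6, and 0 to 0 and 0 to 24 for Listeria. The heat shock median in control DCV flies at 72 h ran from −0.0063 without control DCV 72 h replicate 1 to 0.25 without replicate 2, and the Imd peptide median in knockdown Listeria flies at 72 h from −0.61 without knockdown Listeria 72 h replicate 2 to 5.01 without replicate 1.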

Other observations

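The contrasts here were chosen only after results were seen, and their genes after their values were seen.

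DCV and Listeria were compared with each other in control flies at 72 h, where 508 probe sets were higher after DCV and 277 after Listeria. CG7763 was higher after DCV by 5.05, CG32302 by 4.63 and the stress peptide TotC by 4.29. The galactose-binding lectin gene Lectin-galC1 stood at −4.50 (SE 0.3153, adjusted p = 1.036e-09), the immune-induced gene edin at −6.54 and CecB at −3.92. In knockdown flies at 72 h 2504 probe sets differed between the inocula, and in control flies at 24 h 1, CG10910 at 1.34.

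In mock control flies, 7032 probe sets differed between 72 and 24 h, but 1136 without control mock 24 h replicate 3 and 145 without replicates 3 and 4. In mock knockdown flies, 139 probe sets differed between 72 and 24 h, and 673 without control mock 24 h replicate 3 and 1069 without replicates 3 and 4, which enter this contrast only through the pooled variance. CG5892 was higher at 72 h by 1.88 and Dgat2, of triglyceride synthesis, by 1.37, while the bomanins BomBc3 and BomS5 stood at −2.30 and −1.88. In DCV flies at 72 h, knockdown and control flies differed at 439 probe sets, 367 higher and 72 lower in knockdown flies. CG14219, y and CG14205 were higher by 3.10, 3.06 and 2.55, and the eggshell genes dec, Vm32E and Vm26Ac stood at −5.23, −4.43 and −4.22. In Listeria flies at 72 h they differed at 60, with CecB at −3.70 and spirit at −2.80. CecB stood at 5.59 and 8.15 on the knockdown Listeria arrays 1 and 2, against a mock mean of 5.99, and at 10.3 and 10.8 on the control Listeria arrays.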
